A study of Mus musculus with 12 samples.

How the data were processed

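Polyadenylated RNA was sequenced from 12 libraries of mouse cells in 4 groups, which the labels name by cell type and genotype: WT mESC (n = 2), EED-/- mESC (n = 2), WT AntNPC (n = 4) and EED-/- AntNPC (n = 4). The mESC are mouse embryonic stem cells grown in serum with LIF on gelatin, and the WT cells are the E14 line. The AntNPC are anterior neural progenitors made from them in 5 days in serum-free N2B27 medium, with bFGF at 10 ng/ml for the first 3 days and the WNT inhibitor Xav939 at 5 uM from day 2, per the labels' protocols. Libraries were made with a TruSeq v2 kit, per the labels' protocols. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Each genotype is represented by 1 cell line, and the parental line and the allele of the EED-/- line are not given in the sources used here, so other differences between the lines are not separated from the genotype.

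The authors deposited 1 table of 21253 genes, with an Ensembl gene ID and a symbol for each. Its 12 columns of single libraries were taken as FPKM (fragments scaled by transcript length and library size) made by the authors with Cufflinks after TopHat2 alignment to GRCm38 (mm10), per the submitters' processing notes, which also name FastQC and SAMtools; versions, annotation and parameters are not given in the sources used here. The table's header does not name the unit, and the values fit FPKM in that they are not whole numbers and their sums differ between libraries. Further deposited columns hold the authors' mean FPKM per group, and for AntNPC the authors' mean read count per group (a normalized signal that is not whole) and a p-value from the authors' comparison. DESeq2 is named in the submitters' processing notes for 8 of the 12 libraries, and the authors' p-value is not stated to be adjusted or unadjusted. Columns were matched to samples by name, and 0 columns of per-sample values were left unused. The replicate without a number in its title was taken as replicate 1.

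FPKM keep no read depth, so the depth per library is unknown and no counting interval is given. The sum of FPKM ran from 453550 to 864235 per library. An exact 0 can be a failed estimate: Gapdh was listed at 0 in WT AntNPC replicate 1 against a median of 2080 FPKM in the other 11 libraries, and Rpl22 in EED-/- AntNPC replicate 1 against 1330. Where a group holds an exact 0, single values are given in place of a mean.

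Values were transformed as log2(FPKM + 1), which understates the change of genes of low FPKM, and every log2 fold change is on that scale. The 13678 genes of at least 1 FPKM in at least 2 libraries were tested with limma 3.58.1 (limma-trend, R 4.3.3) in 1 model of the 4 group means over all 12 libraries, with 8 residual and 2.93 prior degrees of freedom, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The AntNPC libraries therefore contribute to the spread against which the mESC groups of 2 were tested. The 5 comparisons were EED-/- against WT in AntNPC, EED-/- against WT in mESC, AntNPC against mESC in WT, AntNPC against mESC in EED-/-, and the difference between the last pair (the interaction). "Rose" and "fell" below mean an adjusted p under that threshold.

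The gene lists and the rule for genes named in the text were fixed before the data were examined. The 23 lists, from textbook knowledge, were study poised enhancer targets, PRC2 subunits, PRC1 subunits, pluripotency, formative epiblast, anterior neural regulators, pan-neural progenitor, Hox genes, posterior neural and tailbud, primitive streak and mesoderm, endoderm, trophoblast, neural crest and surface ectoderm, postmitotic neuron, fibroblast, WNT targets, BMP and TGF-beta signalling, imprinted genes, germline and 2-cell genes, cell cycle inhibitors and senescence, proliferation, stress response, and sex chromosome line markers. The study's own targets were known from the study and are not independent evidence of direction. Members were counted over all tested genes and also adjusted over the list alone. Each list was tested against all other genes with camera (limma) at a preset inter-gene correlation of 0.01, Benjamini-Hochberg over the 23 lists, and again with an estimated correlation; fry, which tests whether the members move one way on balance without reference to other genes, was an alternative.

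The rule for genes named in the text took Eed, the other PRC2 subunits and the 5 study targets. In each comparison it took the 6 genes with the largest rise and the 6 with the largest fall whose groups did not overlap. Their higher group had to have a mean of at least 5 FPKM, and predicted and RNA genes were left out by symbol. From each list it took up to 2 members per direction with the smallest adjusted p. Where 5 or fewer members passed in a direction, it took all of them. Gene positions are from GENCODE M21 on GRCm38, which matched 21149 of the 21253 genes by Ensembl gene ID. Some genes that the rule picks are not reported here. Of the 82 genes named by this rule, 23 share exon bases with an annotated gene on the opposite strand, among them Eed, Six3, Lhx5, Hoxa7, Igf2 and Mid1. The labels do not say whether the counting used strand, so their values can hold reads of that partner. Igf2 also shares 3596 exon bases with a gene on the same strand, and Fgfr2, Gata3 and Sox1 share fewer. Counting by strand would not separate those. Xlr3a, Dppa3, Dppa5a and Krt8 have close copies elsewhere in the genome, and how reads were divided among copies is not given, so their levels are uncertain.

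The steps were tested on simulated data with 200 genes changed by known folds. In the AntNPC comparison 62% of 2-fold and 92% of 4-fold changes were recovered with 13 false calls among 167; in the mESC comparison 32% and 76%, with 5 among 113; in WT differentiation 38% and 89%, with 5 among 132; and for the interaction 11% and 58%, with 5 among 74.

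Replicate numbers are shared between groups. In AntNPC the deviations of same-numbered libraries from their group means correlated across genes at 0.56, 0.32, 0.42 and 0.33 for replicates 1 to 4, all above 0.1, so the numbers were taken to pair the AntNPC libraries, as read from the data and not stated in the labels. For replicates 2 and 4 another number correlated better (0.4 for each), so the pairing of replicates 2 to 4 is not specific to the number. In mESC the correlation was -0.67. The fit with the number as a block was an alternative, and its value stands beside a result where it changed a call or moved a count by over 1.5 times. Other alternatives were a pseudocount of 0.1, no filter on low values, median-ratio scaling, quantile normalization, a term for the deposition batch, no intensity trend, the compared groups alone, a fold of at least 2, and leaving out each replicate. Alternatives chosen after seeing the data were a block with the mESC numbers crossed, leaving out the genes of chromosomes 3, 6 and 8, replacing doubtful zeros, AntNPC replicates 2 to 4 alone (the numbered titles, called the second deposition), AntNPC libraries alone with the block, and the mESC groups without the 2 libraries of highest or of lowest total FPKM.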

Results

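Gene expression was measured in 12 RNA-seq libraries of mouse embryonic stem cells (mESC) and of anterior neural progenitors (AntNPC) derived from them, from a WT line and a line labelled EED-/-. EED is a core subunit of PRC2, the complex that methylates lysine 27 of histone H3 at silent developmental genes. The series' title places the comparison in a study of PRC2 and poised enhancers, which lie near genes that are induced later in differentiation. There were 2 libraries of each mESC group and 4 of each AntNPC group. The sum of FPKM per library was 453550 and 864235 in WT mESC, 788753 and 475689 in mESC labelled EED-/-. It was 469864 to 539608 in WT AntNPC and 455577 to 542958 in AntNPC labelled EED-/-. The share of it held by ribosomal protein genes was 16.3% and 32.7% in WT mESC, 25.4% and 10.9% in mESC labelled EED-/-. It was 14% to 22.7% in WT AntNPC and 11.3% to 19.6% in AntNPC labelled EED-/-. In both AntNPC groups replicate 1 stood apart: across genes, replicates 2 to 4 of WT correlated with each other at 0.996 to 0.997 and with replicate 1 at 0.963 to 0.964. The correlations were 0.996 and 0.956 to 0.96 in those labelled EED-/-.

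Eed itself (chromosome 7, 89954654 to 89980983, GRCm38) was not lower in the libraries labelled EED-/-. Its FPKM was 66.2 and 163 in WT mESC against 644 and 376 in mESC labelled EED-/-. In AntNPC it was 42, 54.7, 63.4 and 61.7 in WT against 182, 171, 202 and 186 in EED-/-. The log2 fold change was 1.74 ± 0.27 (SE; limma, adjusted p = 0.000616) in AntNPC and 2.23 ± 0.38 (adjusted p = 0.00163) in mESC. In the authors' deposited table the mean read count of Eed went the other way in AntNPC, 3723.13 in WT and 2495.77 in EED-/-, a ratio of 0.67. The allele is not given in the sources used here, so the level of Eed RNA does not check the loss of the protein, and its FPKM goes against the label. Every direction given here rests on the labels. Of the other PRC2 subunits, Rbbp4, a histone-binding subunit shared with other complexes, fell from 126 ± 4.81 to 82.8 ± 2.29 FPKM (SD, n = 4) in AntNPC. In mESC it fell from 107 ± 12.3 to 65.1 ± 2.94 FPKM (SD, n = 2). Phf19, an accessory subunit, rose in AntNPC from 2.09 ± 0.331 to 7.17 ± 0.793 FPKM. The PRC2 list had 3 members that rose and 1 that fell of 12 tested in AntNPC (camera adjusted p = 0.569), and 1 and 1 in mESC (0.778).

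The comparison of AntNPC asked what loss of EED changes after neural differentiation. AntNPC labelled EED-/- had lower levels of midbrain and forebrain regulators and higher levels of Hox, mesoderm, endoderm, trophoblast, neural crest and pluripotency genes, of which the pluripotency call was lost with an estimated correlation (adjusted p = 0.122). Wnt1, a signal of the midbrain-hindbrain boundary, fell from 151 ± 78.8 to 7.25 ± 1.06 FPKM (SD, n = 4). It was 34.6 FPKM in WT replicate 1 and 180 to 208 in the other 3 WT libraries. Pax2 and En1, paired-box and homeobox genes of the same region, fell from 35.4 ± 5.87 to 1.89 ± 1.44 FPKM and from 32.7 ± 11.3 to 1.96 ± 0.655 FPKM. Cdkn2a, which encodes the cell cycle inhibitors p16 and p19Arf and is a known Polycomb target, rose from 1.05 ± 0.418 to 85.7 ± 16.8 FPKM, a log2 fold change of 5.40 ± 0.21. Across the 13678 genes tested 2507 rose and 1060 fell, of which 1252 and 410 changed at least 2-fold. At an unadjusted p under the threshold there were 4908 genes.

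Of the 5 genes that the study names as poised enhancer targets, 3 fell, and because the study chose them this is not independent evidence of direction. Wnt8b (chromosome 19, 44493472 to 44514273), a WNT ligand of the early forebrain, fell from 10.5 ± 1.19 to 0.303 ± 0.287 FPKM (SD, n = 4; log2 fold change -3.16 ± 0.15, limma adjusted p = 3.91e-07). Lmx1b (chromosome 2, 33560965 to 33640511), a homeobox gene of the midbrain, fell from 29.8 ± 3.11 to 7.12 ± 0.845 FPKM (-1.92 ± 0.17). Lhx5 (chromosome 5, 120431699 to 120441223), a forebrain homeobox gene, fell from 8.92 ± 7.23 to 0.804 ± 0.407 FPKM (-2.26 ± 0.36). WT replicate 1 held 19.7 FPKM and the other 3 WT libraries 4.75 to 6.03. Sox1 (chromosome 8, 12395295 to 12400126), a pan-neural factor, had 14.9 ± 1.25 and 12.2 ± 2.06 FPKM (-0.28 ± 0.16, adjusted p = 0.246). It passed downward with replicates 2 to 4 alone (-0.34, limma adjusted p = 0.00238) and with the AntNPC libraries alone and the block (-0.28, 0.0241). Genes of chromosome 8 were higher as a group in AntNPC labelled EED-/-, by a median log2 shift of 0.46, which Sox1 did not follow. Six3 (chromosome 17, 85613608 to 85629302), a forebrain and eye regulator, had 25.7 FPKM in WT replicate 1 and 5.09 to 5.31 in the other 3 WT libraries, against 12.8 to 14.1 in those labelled EED-/-. Its log2 fold change was 0.69 ± 0.41 (adjusted p = 0.265). Without WT replicate 1 it was 1.22, with an adjusted p of 6e-05. The list as a whole was lower (camera adjusted p = 0.000671; adjusted p = 0.0659 with an estimated correlation), and adjusted over the list alone 0 rose and 3 fell.

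**Figure D1:**
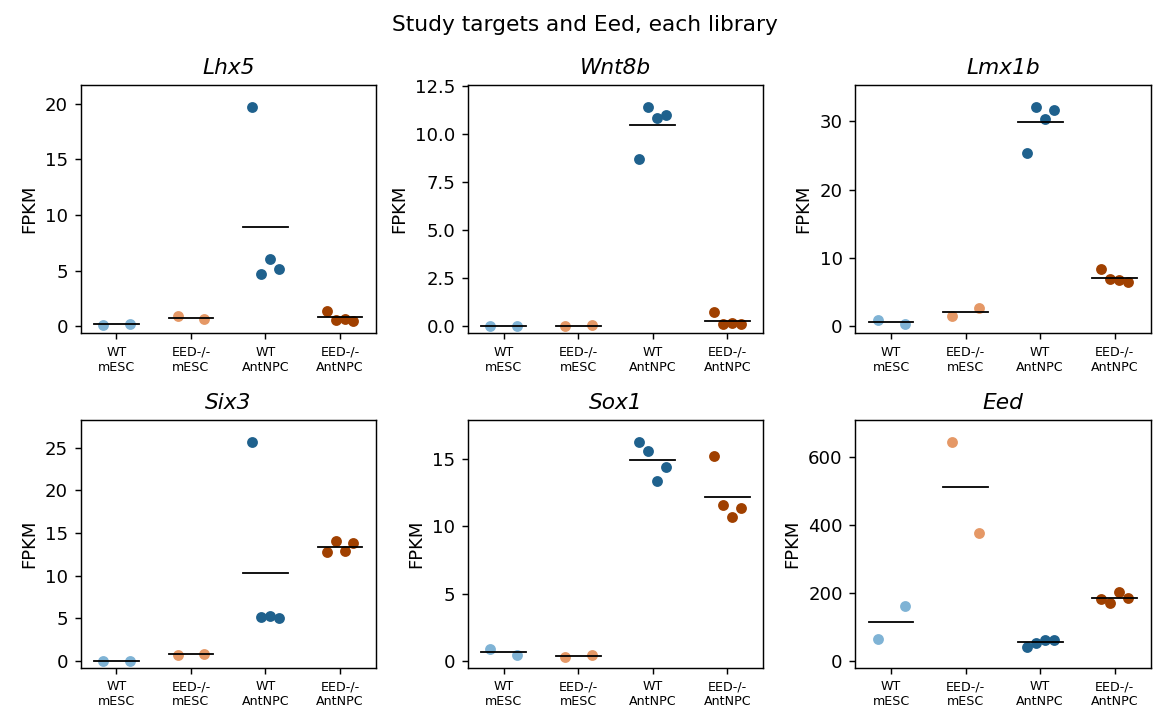
FPKM (vertical axis) of Lhx5, Wnt8b, Lmx1b, Six3, Sox1 and Eed in each library (points) of the 4 groups (horizontal axis), with bars at the group means. Bars are also drawn where a library is listed at 0, as for Six3 and Wnt8b in WT mESC. Wnt8b lies at 8.72 to 11.4 FPKM in WT AntNPC and at 0.128 to 0.731 in AntNPC labelled EED-/-, while Eed lies higher in the libraries labelled EED-/-.

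Anterior neural regulators were mostly lower: 20 of 34 tested members fell, 3 rose and 11 did not pass (camera adjusted p = 9.51e-11; 0.0169 with an estimated correlation). Fezf1, a forebrain zinc finger factor, fell from 21.5 ± 1.26 to 2.26 ± 0.588 FPKM (SD, n = 4). Among those that rose were Emx1, a cortical homeobox gene, from 0.235 ± 0.0969 to 1.53 ± 0.316 FPKM, and Vax1, a ventral forebrain homeobox gene. Vax1 was listed at 0 to 0.0912 FPKM in the WT libraries and at 1.36 to 1.88 in those labelled EED-/-. Emx1 did not pass after quantile normalization (log2 fold change 0.51, adjusted p = 0.148). Among pan-neural progenitor genes 12 of 24 fell and 3 rose (adjusted p = 1.01e-05; adjusted p = 0.122 with an estimated correlation). Sox21 and Sox3, SOX factors of neural progenitors, fell from 29.1 ± 7.13 to 1.72 ± 1.23 FPKM and from 30.5 ± 1.35 to 9.66 ± 2.28 FPKM, whereas Zic1, a neural plate zinc finger factor, rose from 1.21 ± 0.732 to 14.3 ± 0.788 FPKM. WNT targets went both ways, 2 rising and 3 falling of 11 (adjusted p = 0.221). Among the 3 that fell were Axin2 and Apcdd1, from 43.4 ± 10.7 to 7.05 ± 1.46 FPKM and from 26.5 ± 1.63 to 2.24 ± 0.359 FPKM. Adjusted over the list alone, 23 anterior neural regulators fell and 5 rose, 14 pan-neural genes fell and 3 rose, and 3 WNT targets fell and 2 rose.

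All 27 tested Hox genes, which pattern the hindbrain and trunk, rose (camera adjusted p = 3.7e-23, and 0.0169 with an estimated correlation). Their median log2 fold change was 1.90, and under quantile normalization 24 of the 27 passed. The table holds 38 Hox genes, and those that did not reach 1 FPKM in at least 2 libraries were not tested. A gene near 0 in WT could enter the test only through the libraries labelled EED-/-, so 27 of 27 is not a share of all Hox genes. The same filter left 23 of 30 mesoderm, 23 of 26 endoderm, 12 of 15 trophoblast and 16 of 20 neural crest and surface ectoderm genes. Shares of these lists, here and in mESC, are likewise of the tested members alone, and the camera p-values cover only those members. Hoxa7 was listed at 0 to 0.0354 FPKM in WT AntNPC and at 6.02 to 6.26 in AntNPC labelled EED-/-, and Hoxb8 at 0 to 0.034 and 4.19 to 5.54. Primitive streak and mesoderm genes rose in 21 of 23 cases (1.93e-16; 0.0116 with an estimated correlation). Foxc1, a paraxial mesoderm factor, rose from 0.104 ± 0.00914 to 2.73 ± 0.301 FPKM (SD, n = 4). In the endoderm list 15 of 23 rose and 1 fell (2.32e-05; 0.0169 with an estimated correlation). Gata4 and Foxa2, endoderm transcription factors, rose from 0.357 ± 0.125 to 10.6 ± 1.5 FPKM and from 0.124 ± 0.0233 to 2.77 ± 0.435 FPKM. Trophoblast genes rose in 10 of 12 cases (4.47e-08; 0.0169 with an estimated correlation). The placental homeobox gene Esx1 rose from 0.383 ± 0.245 to 20 ± 1.14 FPKM, and Gata3, a trophoblast factor, from 0.181 ± 0.0637 to 4.97 ± 0.758 FPKM. Of 16 neural crest and surface ectoderm genes 11 rose and 1 fell (4.17e-05; 0.0169 with an estimated correlation). Tfap2a, a neural crest factor, rose from 0.66 ± 0.285 to 11.5 ± 1.9 FPKM and the craniofacial homeobox gene Dlx5 from 0.214 ± 0.12 to 6.29 ± 1.64 FPKM. The 1 that fell was Sox9, which acts in neural crest and in neural progenitors, from 19.9 ± 4.12 to 4.52 ± 0.398 FPKM. The counts adjusted over the list alone were 27 rising Hox genes, 22 mesoderm, 16 endoderm with 1 falling, 10 trophoblast, and 11 neural crest with 1 falling.

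Pluripotency genes were also higher: 20 of 25 rose and 0 fell (camera adjusted p = 9.49e-09; adjusted p = 0.122 with an estimated correlation; 20 and 0 adjusted over the list alone). Dppa3, expressed in naive stem cells and germ cells, rose from 0.486 ± 0.243 to 29.3 ± 10.5 FPKM (SD, n = 4). Esrrb, a naive pluripotency factor, rose from 0.766 ± 0.25 to 8.24 ± 0.892 FPKM against 131 ± 20.3 FPKM (SD, n = 2) in WT mESC. Germline and 2-cell genes rose in 10 of 20 cases (0.000439; adjusted p = 0.156 with an estimated correlation). The X-linked homeobox gene Rhox5 rose from 1.61 ± 0.222 to 93.7 ± 27.7 FPKM. Fibroblast genes rose in 9 of 10 cases (9.28e-06; adjusted p = 0.136 with an estimated correlation). Acta2, smooth muscle actin, rose from 1.36 ± 0.273 to 25.3 ± 9.06 FPKM. In BMP and TGF-beta signalling 9 of 17 rose (0.000116; adjusted p = 0.0659 with an estimated correlation). The ligand Tgfb1 rose from 0.199 ± 0.0811 to 5.6 ± 0.672 FPKM. In the stress response 5 of 15 rose (0.00545; 0.0453 with an estimated correlation). The numbers that rose adjusted over the list alone were 10 germline, 10 fibroblast, 11 BMP and TGF-beta and 6 stress genes. Of the cell cycle inhibitors and senescence genes 3 of 10 rose and 4 fell (0.785; median log2 fold change -0.12, mean 0.34). Among those that fell were Trp53 and its targets Cdkn1a and Ccng1, which act in cell cycle arrest. Trp53 fell from 109 ± 2.7 to 39.3 ± 5.58 FPKM, Cdkn1a from 27.1 ± 15 to 3.95 ± 1.76 FPKM and Ccng1 from 79.8 ± 28.6 to 12 ± 0.473 FPKM.

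The other lists did not pass camera in AntNPC: PRC1 subunits (6 rose and 2 fell of 20, adjusted p = 0.785), formative epiblast (4 and 0 of 10, 0.106), and posterior neural and tailbud (8 and 2 of 16, 0.264; 4 and 4 under quantile normalization). Nor did postmitotic neuron (5 and 4 of 18, 0.621; 3 and 5 under quantile normalization), imprinted (9 and 4 of 25, 0.173), proliferation (2 and 1 of 18, 0.621) and sex chromosome line marker genes (0 and 0 of 5, 0.397). The largest changes also included X-linked genes with no list. Hprt, a purine salvage enzyme, rose from 0.844 ± 0.29 to 46.4 ± 9.98 FPKM (SD, n = 4), and Xlr3a, of a lymphocyte-regulated family, from 0.36 ± 0.195 to 34.6 ± 1.58 FPKM. Mid1, a microtubule-associated ubiquitin ligase, fell from 371 ± 69.2 to 4.93 ± 0.552 FPKM, and Irs4, an insulin receptor substrate, from 28.8 ± 6.02 to 1.49 ± 0.826 FPKM. Cldn6, a tight junction protein of early epithelia, rose from 2.88 ± 0.934 to 96 ± 6.66 FPKM. Genes of chromosomes 3, 6 and 8, among them Hoxa7, Dppa3 and Emx1, were higher as a group in the libraries labelled EED-/-. Over genes of mean FPKM above 5 the median log2 shifts from the other autosomes were 0.57, 0.63 and 0.46 in AntNPC and 0.45, 0.61 and 0.50 in mESC. These chromosomes hold 14.7% of tested genes and 31.9% of those that rose in AntNPC.

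**Figure D2:**
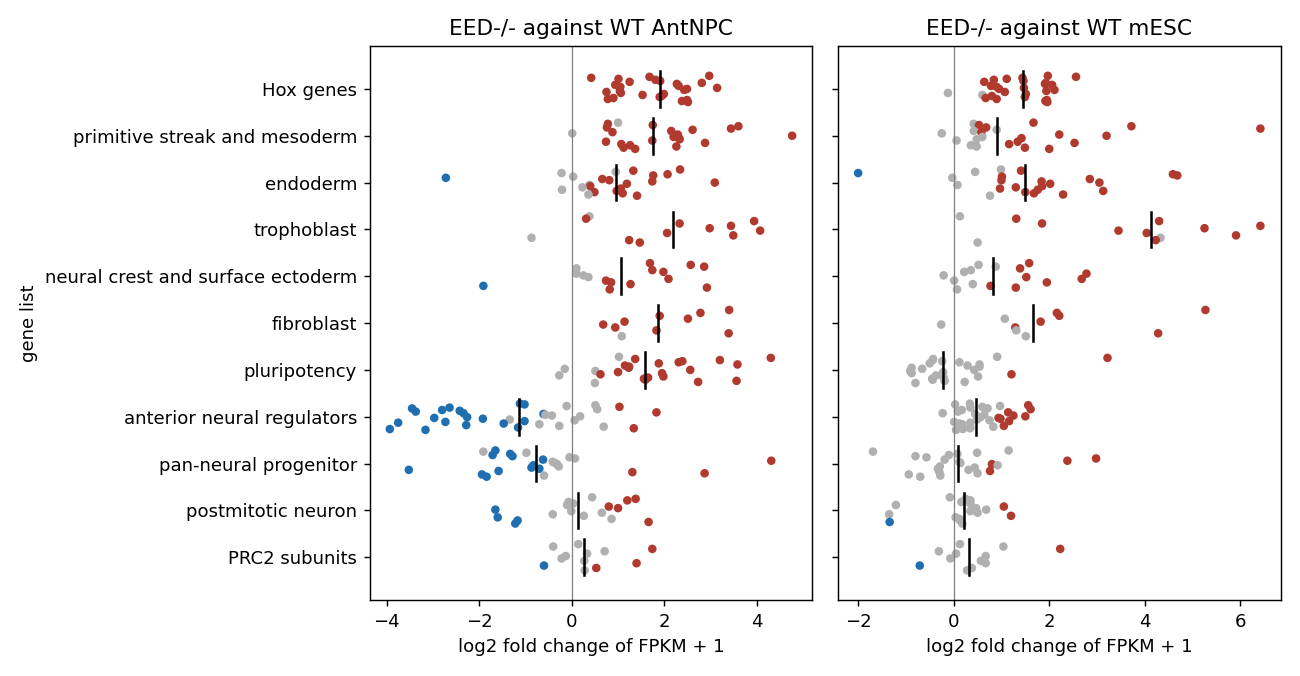
Log2 fold change of FPKM + 1 (horizontal axis) of each tested member of 11 gene lists (vertical axis) for EED-/- against WT in AntNPC and in mESC; red rose, blue fell, grey did not pass, and the black line is the list's median. In AntNPC all 27 Hox genes lie to the right and 20 of 34 anterior neural regulators are blue.

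With the replicate number as a block 1955 genes rose and 697 fell in AntNPC, with the 8 AntNPC libraries alone 4323 and 2800, without the genes of chromosomes 3, 6 and 8 1657 and 944, and without WT mESC replicate 1 or 2 the number that fell was 1669 or 1662. The share of changed genes that rose was 70.3%, and 50% under quantile normalization, where the median of all genes was -0.06 in place of 0.05.

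Of the 21253 genes deposited, 11091 had an authors' p under 0.05, 5716 of them higher and 5375 lower in EED-/-. Among the genes tested here 9315 did. That p is not stated to be adjusted, so these counts are not on the same footing as the calls here. Of 3549 genes called here that have a mean read count above 0 in both groups, 3542 (99.8%) had the same direction there and 7, Eed among them, the opposite one. Across genes, which are not independent replicates, the log2 changes correlated at 0.84. Both comparisons come from the same deposited AntNPC data, so their agreement is not independent evidence.

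The comparison of mESC asked what loss of EED changes before differentiation. Many trophoblast, endoderm, mesoderm and Hox genes were higher in mESC labelled EED-/-, while most pluripotency genes did not pass the test. The mesoderm and Hox list calls were lost with an estimated correlation (both adjusted p = 0.0707), and with the mESC libraries alone limma called 0 genes (1703 at an unadjusted p under the threshold). Igf2, an imprinted growth factor, rose from 2.99 ± 2.67 to 1050 ± 565 FPKM (SD, n = 2; log2 fold change 8.11 ± 0.47, limma adjusted p = 1.9e-06). Hand1, a regulator of trophoblast and extraembryonic mesoderm, rose from 0.331 ± 0.0213 to 122 ± 66 FPKM. Krt8, a keratin of simple epithelia, rose from 8.68 ± 2.97 to 619 ± 350 FPKM, and Rhox6, a reproductive homeobox gene, from 3.41 ± 2.4 to 312 ± 167 FPKM. Across the genes tested 2732 rose and 373 fell.

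Of 12 trophoblast genes 9 rose (camera adjusted p = 3.07e-09; 0.0293 with an estimated correlation). Plac1, a placental gene, was listed at 0 and 0.0252 FPKM in WT mESC and at 19.6 and 16.5 in mESC labelled EED-/-. Endoderm genes rose in 17 of 23 cases and fell in 1 (7.12e-08; 0.0147 with an estimated correlation). Sox17, an endoderm regulator, rose from 0.178 ± 0.17 to 9.55 ± 3.51 FPKM (SD, n = 2) and Col4a2, a basement membrane collagen, from 3.03 ± 1.83 to 100 ± 35.8 FPKM. Hox genes rose in 25 of 27 cases (9.87e-14; adjusted p = 0.0707 with an estimated correlation), and 16 passed under quantile normalization. Hoxa7 rose from 0.0463 ± 0.0059 to 3.02 ± 0.833 FPKM and Hoxd8 from 0.119 ± 0.0788 to 3.24 ± 0.205 FPKM. Mesoderm genes rose in 14 of 23 cases (5.33e-06; adjusted p = 0.0707 with an estimated correlation) and neural crest and surface ectoderm genes in 8 of 16 (0.0148; adjusted p = 0.127 with an estimated correlation; 4 rose and 1 fell under quantile normalization). The epidermal keratin gene Krt14 rose from 0.0873 ± 0.0308 to 6.59 ± 2.09 FPKM. Fibroblast genes rose in 6 of 10 cases (0.00552; adjusted p = 0.549 with an estimated correlation), such as Acta2, from 0.309 ± 0.13 to 49.9 ± 9.73 FPKM. In the pluripotency list 2 of 25 rose and 0 fell. They were Dppa3, from 7.56 ± 0.519 to 83.4 ± 39.7 FPKM, and Prdm14, a germ cell and naive pluripotency factor, from 5.31 ± 2.37 to 13.5 ± 4.71 FPKM. The list's camera call was downward (0.047; adjusted p = 0.615 with an estimated correlation), with a median log2 fold change of -0.22, a mean of 0.01 and an upward direction in fry (0.897). Adjusted over the list alone 10 trophoblast genes rose, 17 endoderm genes rose and 1 fell, and 26 Hox, 16 mesoderm, 9 neural crest, 9 fibroblast and 2 pluripotency genes rose.

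Among the largest falls in mESC were Mid1, from 328 ± 32.5 to 1.96 ± 0.936 FPKM (SD, n = 2), and Ephx2, an epoxide hydrolase, from 72.6 ± 27.7 to 8.42 ± 1.31 FPKM. Dhx16, an RNA helicase, fell from 286 ± 111 to 43.2 ± 19.3 FPKM, and Dpys, dihydropyrimidinase, from 43.7 ± 6.97 to 6.11 ± 2.46 FPKM. Eda2r, a receptor gene, and Sycp3, a meiotic chromosome protein, had log2 fold changes of -3.02 ± 0.72 and -2.93 ± 0.66. Eda2r did not pass without EED-/- mESC replicate 1 (adjusted p = 0.0533), nor Sycp3 without replicate 2 (0.0504). Ccng1 fell from 68.4 ± 44.2 to 13.2 ± 3.22 FPKM. Hprt rose from 0.513 ± 0.0614 to 79.6 ± 4.48 FPKM, and Cdkn2a from 18.5 ± 2.15 to 90 ± 28.7 FPKM. Of the 5 study targets Lmx1b rose, from 0.597 ± 0.426 to 2.13 ± 0.748 FPKM (adjusted p = 0.0152; 0.075 with the block). It did not pass under quantile normalization (0.195) or without EED-/- mESC replicate 2 (0.0885). Prdm14 did not pass without that library (0.0743). The list did not pass (0.927).

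With the 4 mESC libraries alone, limma called 0 genes in either direction in this comparison of 2 against 2 (smallest adjusted p = 0.0528, with 1703 genes at an unadjusted p under the threshold), so the mESC calls rest on the spread shared with AntNPC; with the block 1735 rose and 190 fell, and without WT mESC replicate 1 or 2 the number that fell was 716 or 1366. The median log2 fold change of all genes was 0.29, 0.07 after median-ratio scaling and -0.05 after quantile normalization, and the share of changed genes that rose was 88%, 70.9% and 52.2%.

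AntNPC were next compared with mESC within WT, to describe the programme that differentiation turns on and off. In WT, most tested anterior and pan-neural genes rose and most pluripotency genes fell, though these list calls were lost with an estimated correlation (adjusted p = 0.0545, 0.197 and 0.0905). Ptn, a growth factor of neural progenitors, rose from 0.277 ± 0.277 FPKM (SD, n = 2) to 172 ± 62.5 FPKM (SD, n = 4), and the WNT secretion factor Wls from 0.559 ± 0.282 to 188 ± 74.6 FPKM. Tdgf1, a NODAL co-receptor, fell from 457 ± 161 to 0.729 ± 0.394 FPKM, and Esrrb from 131 ± 20.3 to 0.766 ± 0.25 FPKM. There were 4117 genes that rose and 2471 that fell (62.5% rose; 50.9% after median-ratio scaling, where the median of all genes was -0.02 in place of 0.17).

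All 5 study targets rose (camera adjusted p = 0.000612; adjusted p = 0.0938 with an estimated correlation; 5 adjusted over the list alone). Sox1 rose from 0.688 ± 0.348 to 14.9 ± 1.25 FPKM, and Lmx1b and Lhx5 had log2 fold changes of 4.29 ± 0.21 and 2.83 ± 0.44. Those of Wnt8b and Six3, each listed at 0 in 1 WT mESC library, were 3.50 ± 0.19 and 3.15 ± 0.50. Of 34 anterior neural regulators 30 rose and 0 fell (2.04e-12; adjusted p = 0.0545 with an estimated correlation), such as Wnt1, listed at 0 and 0.281 FPKM in WT mESC, and Fezf1, listed at 0 and 0.0346. Of 24 pan-neural genes 17 rose and 1 fell (7.65e-06; adjusted p = 0.197 with an estimated correlation), such as Sox3, from 0.853 ± 0.0101 to 30.5 ± 1.35 FPKM. Of 25 pluripotency genes 23 fell and 1, the RNA-binding protein gene Lin28a, rose from 80.6 ± 23.2 to 226 ± 29.1 FPKM (1.19e-16; adjusted p = 0.0905 with an estimated correlation). Tbx3, a naive pluripotency factor, fell from 30.3 ± 8.1 to 0.169 ± 0.0285 FPKM, and Zfp42, a stem cell marker, from 295 ± 233 to 1.67 ± 0.314 FPKM. Germline and 2-cell genes fell in 14 of 20 cases (2.78e-07; adjusted p = 0.0938 with an estimated correlation). The meiotic gene Hormad1 fell from 28.6 ± 11.4 to 0.097 ± 0.0516 FPKM. Stress genes fell in 7 of 15 cases with 1 rising (0.00598; adjusted p = 0.0905 with an estimated correlation). Hox genes did not pass (0 rose and 4 fell of 27, 0.108), nor did trophoblast genes (0 and 5 of 12, 0.0608), but both passed downward with the block (0.0397 and 0.0301) and not with an estimated correlation (0.602 and 0.48). Adjusted over the list alone 30 anterior neural and 18 pan-neural genes rose, and 23 pluripotency, 14 germline and 7 stress genes fell.

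Other large rises in WT were Prtg, an immunoglobulin superfamily receptor, from 0.504 ± 0.0305 to 133 ± 11.5 FPKM, and Sall2, a zinc finger factor, from 0.859 ± 0.0769 to 115 ± 5.7 FPKM. Crabp2, a retinoic acid binding protein, rose from 8.07 ± 1.3 to 475 ± 124 FPKM. Large falls were those of Dppa5a, an RNA-binding protein of stem cells (log2 fold change -7.88 ± 0.65), and Upp1, uridine phosphorylase (-7.44 ± 0.43). The chaperone gene Hspb1 (-6.74 ± 0.46) and the glutathione peroxidase gene Gpx2 (-6.64 ± 0.49) also fell. Eed had 114 ± 68.2 FPKM (SD, n = 2) in WT mESC and 55.5 ± 9.71 (SD, n = 4) in WT AntNPC, a log2 fold change of -0.91 ± 0.33 (limma adjusted p = 0.0397). It did not pass with the block (0.0805), with no filter (0.0554), with the WT libraries alone (0.0967), without any 1 of the 8 AntNPC libraries (0.051 to 0.0886) or without WT mESC replicate 2 (-0.27, adjusted p = 0.475).

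The same comparison was made in the line labelled EED-/-. Most pluripotency genes fell and most pan-neural and anterior neural genes rose, list calls that were lost with an estimated correlation (adjusted p = 0.0932, 0.107 and 0.069). Esrrb reached 8.24 ± 0.892 FPKM (SD, n = 4) from 111 ± 25.7 FPKM (SD, n = 2), and Tbx3 3.66 ± 0.67 from 42.8 ± 3.81 FPKM. Sox1 rose from 0.364 ± 0.114 to 12.2 ± 2.06 FPKM and Six3 from 0.785 ± 0.107 to 13.4 ± 0.675 FPKM. Ptn rose from 1.4 ± 0.246 to 89.8 ± 5.27 FPKM and Pax6, a forebrain and eye regulator, from 1.3 ± 0.788 to 13.7 ± 2.32 FPKM. There were 1963 genes that rose and 2282 that fell (46.2% rose), and under quantile normalization 2786 and 2262 (55.2%).

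Of the study targets 3 of 5 rose (camera adjusted p = 0.00745; adjusted p = 0.123 with an estimated correlation; 3 adjusted over the list alone): Sox1, Six3 and Lmx1b (log2 fold change 1.39 ± 0.21). Lhx5 had 0.763 ± 0.189 and 0.804 ± 0.407 FPKM (0.01 ± 0.44, adjusted p = 0.985) and Wnt8b 0.0453 ± 0.0316 and 0.303 ± 0.287 FPKM (0.29 ± 0.19, adjusted p = 0.252). Anterior neural regulators rose in 21 of 34 cases and fell in 2 (9.26e-07; adjusted p = 0.069 with an estimated correlation). The 2 were the midbrain genes En2 (-0.81 ± 0.25, adjusted p = 0.0321) and Lmx1a (-0.59 ± 0.19, 0.039). Vax1 rose from 0.286 ± 0.0852 to 1.66 ± 0.254 FPKM. Pan-neural genes rose in 15 of 24 cases (3.69e-07; adjusted p = 0.107 with an estimated correlation) and postmitotic neuron genes in 9 of 18 with 1 falling (0.0475; adjusted p = 0.116 with an estimated correlation). Pluripotency genes fell in 22 of 25 cases with 1 rising (3.63e-12; adjusted p = 0.0932 with an estimated correlation). Tdgf1 fell from 325 ± 18.1 to 5.59 ± 6.34 FPKM, with 15 FPKM in AntNPC replicate 1 and 1.79 to 3.23 in the other 3. Trophoblast genes fell in 10 of 12 cases (1.29e-06; adjusted p = 0.069 with an estimated correlation). The keratin gene Krt7 fell from 60.2 ± 14.7 to 3.74 ± 0.334 FPKM and Plac1 from 18.1 ± 2.2 to 1.57 ± 0.316 FPKM. Germline and 2-cell genes fell in 15 of 20 cases (4.39e-08; adjusted p = 0.069 with an estimated correlation), such as Rhox6, from 312 ± 167 to 8.11 ± 0.805 FPKM. Endoderm genes fell in 11 of 23 cases with 1 rising (0.00275; adjusted p = 0.069 with an estimated correlation) and stress genes in 7 of 15 with 1 rising (0.00375; adjusted p = 0.069 with an estimated correlation). The Hox list did not pass (9 rose and 5 fell of 27, 0.111). Hoxb8 rose from 0.971 ± 0.0619 to 4.73 ± 0.59 FPKM and Hoxb2 from 0.755 ± 0.313 to 4.06 ± 0.529 FPKM. Adjusted over the list alone 22 anterior neural, 15 pan-neural and 9 postmitotic genes rose, and 22 pluripotency, 11 trophoblast, 16 germline, 11 endoderm and 10 stress genes fell.

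With the block 938 genes rose and 1383 fell, and without WT mESC replicate 1 or 2 or EED-/- mESC replicate 1 or 2 the number that rose was 3117, 3119, 941 or 2975. Eed (log2 fold change -1.41 ± 0.33, limma adjusted p = 0.00793) did not pass without EED-/- mESC replicate 1 (0.11), and En2 and Lmx1a did not with the block (0.142 and 0.0724) or without EED-/- mESC replicate 2 (log2 fold change of En2 -0.29; adjusted p = 0.27 and 0.139). En2 also failed with a pseudocount of 0.1 (0.062), with the EED-/- libraries alone (0.0696) and without EED-/- AntNPC replicate 2, 3 or 4 (0.0582 to 0.0753), and Lmx1a after median-ratio scaling (0.0537), quantile normalization (0.126), without EED-/- mESC replicate 1 (0.0767), without WT AntNPC replicate 4 (0.0526) and without any 1 of the 4 EED-/- AntNPC libraries (0.0617 to 0.0911).

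The interaction tested whether the response to differentiation differed between the lines. In the line labelled EED-/-, 21 of 34 anterior neural genes were lower and 14 of 25 pluripotency genes higher after differentiation than the response in WT would give. Both list calls were lost with an estimated correlation (adjusted p = 0.0798 and 0.12). Cyp26a1, a retinoic acid degrading enzyme, went from 0.159 ± 0.0487 FPKM (SD, n = 2) to 24.1 ± 16 FPKM (SD, n = 4) in WT and from 6.09 ± 1.36 to 1.14 ± 0.358 FPKM in EED-/-. The log2 difference was -5.99 ± 0.56 (limma adjusted p = 0.00012). The receptor gene Fgfr2 went from 1.2 ± 0.126 to 95.3 ± 21.4 FPKM in WT and from 16.6 ± 2.34 to 30.5 ± 3.15 FPKM in EED-/-. Epcam, an epithelial adhesion gene, went from 91.1 ± 8.08 to 5.74 ± 3.14 FPKM in WT and from 117 ± 47.7 to 106 ± 3.12 FPKM in EED-/-. The difference was upward for 545 genes and downward for 1541.

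Of 34 anterior neural regulators 21 differed downward and 1 upward (camera adjusted p = 6.19e-11; adjusted p = 0.0798 with an estimated correlation). Wnt8b differed by -3.21 ± 0.27, Lmx1b by -2.90 ± 0.30, Lmx1a by -3.91 ± 0.28 and Lhx5 by -2.82 ± 0.62 on the log2 scale. For Six3 and Sox1 the differences were -0.14 ± 0.70 (limma adjusted p = 0.939) and 0.02 ± 0.27 (0.983). The 1 upward member was Vax1. The study targets, 3 of 5 downward, passed (0.0205; adjusted p = 0.291 with an estimated correlation). So did pan-neural genes (9 downward and 1 upward of 24, 0.046; adjusted p = 0.614 with an estimated correlation; 0.0543 with the block; 5 and 1 under quantile normalization). Pluripotency genes differed upward in 14 of 25 cases (4.48e-13; adjusted p = 0.12 with an estimated correlation). Esrrb differed by 2.64 ± 0.28, Tbx3 by 1.48 ± 0.28 and Utf1, a chromatin protein of stem cells, by 3.75 ± 0.74. The Hox list passed upward (7 upward and 3 downward of 27, 9.05e-06; adjusted p = 0.312 with an estimated correlation), with Hoxb8 at 1.54 ± 0.17. So did the mesoderm list (9 and 2 of 23, 1.57e-05; adjusted p = 0.12 with an estimated correlation). Endoderm (1 upward and 10 downward of 23, 0.0107; adjusted p = 0.12 with an estimated correlation) and trophoblast genes (0 and 6 of 12, 0.0417; adjusted p = 0.325 with an estimated correlation) passed downward. The WNT targets did not pass (0 and 4 of 11, 0.0611), although Axin2 differed by -3.67 ± 0.36 and Apcdd1 by -4.11 ± 0.37. The WNT ligand gene Wnt7b (-5.31 ± 0.56), Sox9 (-2.68 ± 0.27) and Gpx2 (3.90 ± 0.69) also differed. Adjusted over the list alone 27 anterior neural regulators differed downward and 2 upward, 16 pluripotency genes upward, and 11 Hox genes upward and 4 downward. So did 10 mesoderm genes upward and 2 downward, and 12 endoderm and 7 trophoblast genes downward. Of the rest 9 pan-neural genes differed downward and 2 upward, and 3 study targets downward.

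With the block 275 genes differed upward and 776 downward, and without WT mESC replicate 2 the numbers were 1558 and 2733 (2414 downward without WT mESC replicate 1). The upward share of 26.1% was 41.6% after median-ratio scaling and 46.6% after quantile normalization, and the median of all genes moved from -0.20 to 0.01 under each.

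The comparisons were then set against each other. Of the 4117 genes induced in WT differentiation, 857 (20.8%) were lower in AntNPC labelled EED-/-, which is 80.8% of the 1060 genes that fell there, such as Wnt1, Fezf1 and Sox3. Independent lists would share 319. Both comparisons use the WT AntNPC libraries. In 6 splits that gave each comparison its own 2 of them the overlap was 487 to 581 against 148 to 165. In 50 simulations of unchanged groups the highest overlap was 0 (median 64.5 at unadjusted p under the threshold), a value with no effect in either comparison that does not show what shared libraries add among called genes. The same induced genes included 330 that were higher in AntNPC labelled EED-/- (755 for independent lists). Of the 2471 genes that fell in WT differentiation 1041, Esrrb and Tdgf1 among them, were higher there (453). Both counts also rest on shared WT AntNPC libraries and were not repeated with those libraries split. No library is shared between the genotype comparisons in mESC and AntNPC, where 1233 genes rose in both, such as Hoxa7, Dppa3 and Cdkn2a. Independent lists would share 501 (odds ratio 6.24, 95% confidence interval 5.67 to 6.88, Fisher's exact test, two-sided p = 2.3e-305). There were 82 genes that fell in both, against 29 (Fisher's exact test, odds ratio 3.55, p = 1.78e-18). Both comparisons use the same estimate of each gene's spread, from all 12 libraries, so a gene of small spread is more easily called in both. Fisher's test and the numbers for independent lists do not allow for this, nor for genes that vary together. With the block 568 of the induced genes were lower in AntNPC labelled EED-/- and 820 genes rose in both cell types. Without the genes of chromosomes 3, 6 and 8 the latter number was 740.

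**Figure D3:**
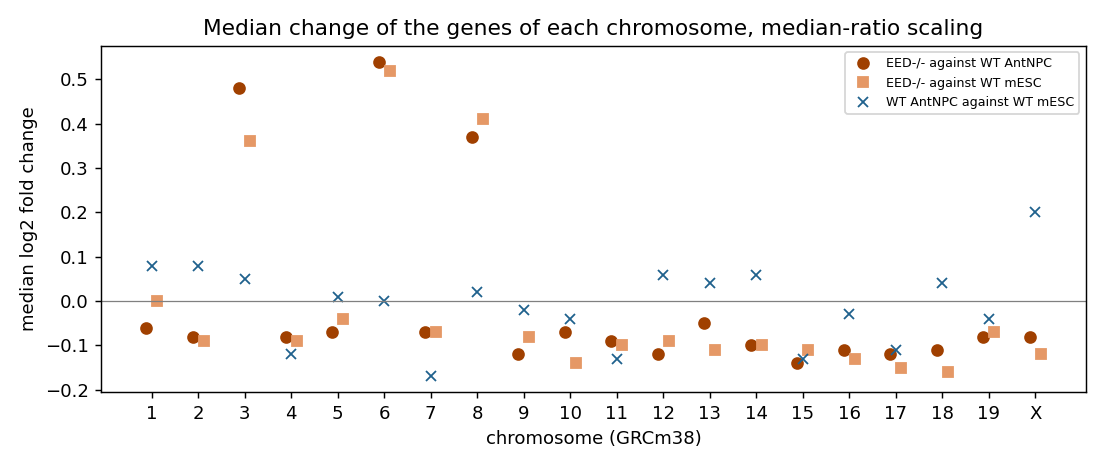
Median log2 fold change of the genes of mean FPKM above 5 of each chromosome after median-ratio scaling (vertical axis) by chromosome (horizontal axis), for EED-/- against WT in AntNPC (circles) and mESC (squares) and for WT AntNPC against WT mESC (crosses). Chromosomes 3, 6 and 8 lie at 0.36 to 0.54 in both EED-/- comparisons, and the other autosomes at -0.16 to 0.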

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

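The tests of extra chromosome copies, of Eed read length, of exchanged labels and of a crossed batch were chosen after the results were seen. The other splits were planned. The tests of GC content and silent genes address a chromosome pattern found in these data. Their predictions were written before their own values were seen, not before the pattern was.

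The 8 AntNPC libraries can be divided into 4 and 4 in 35 ways. The real division gave 3567 genes and the highest of the others 0 (limma; 4908 and 1104 genes at an unadjusted p under the threshold), so 1 of 35 divisions, the real one, gave as many. That share would exclude chance only if the libraries are unpaired, as in the fit without the block, and come from separate cultures. The labels do not say whether they do. In WT AntNPC the replicates other than replicate 1 correlated with each other at 0.996 to 0.997, and with replicate 1 at 0.963 to 0.964. The divisions therefore cannot decide whether chance is excluded. If the numbers pair the libraries, the 8 divisions that part every pair are too few for a share under 0.05. The highest other among those 8 was 0.

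In 29 of 138 tests a single AntNPC library lay far from the other 3 of its group, by Dixon's gap over range, and in each it was replicate 1. Chance gives about 1 in 20. In WT AntNPC replicate 1 the ratios were 0.915 for Lhx5, 0.99 for Six3, 0.838 for Wnt1, 0.897 for Irs4, 0.842 for Sox21, 0.905 for Emx1 and 0.875 for Sox9. They were 0.959 for Cdkn1a, 0.914 for Ccng1, 0.836 for Ptn, 0.94 for Wls, 0.974 for Hspb1 and 0.9 for Lin28a. They were 0.877 for Lmx1a, 0.968 for Cyp26a1, 0.955 for Wnt7b, 0.883 for Fgfr2 and 0.939 for Epcam. In EED-/- AntNPC replicate 1 they were 0.881 for Wnt8b, 0.852 for Pax2, 0.901 for Irs4, 0.944 for Sox21, 0.88 for En1 and 0.872 for Sox3. There they were also 0.949 for Cdkn1a, 0.864 for Wls, 0.892 for Tdgf1, 0.905 for Upp1 and 0.854 for Zfp42. The share of FPKM held by ribosomal protein genes set the same library apart at 0.904. Replicate 1 of both groups was titled apart from replicates 2 to 4, and no explanation was tested for the difference.

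The change between EED-/- and WT differed between AntNPC and mESC for 2086 genes (limma interaction, Benjamini-Hochberg). On the log2 scale the change in AntNPC minus that in mESC was negative for several neural and WNT pathway genes, and positive for the neural genes Zic1 and Vax1. It was -2.82 for Lhx5, -3.21 for Wnt8b, -2.90 for Lmx1b, -3.91 for Lmx1a, -4.12 for Wnt1, -4.10 for Pax2, -4.16 for En1 and -2.97 for Fezf1. It was -3.83 for Sox21, -2.35 for Sox3, -2.68 for Sox9, -3.67 for Axin2, -4.11 for Apcdd1, -5.31 for Wnt7b, -5.99 for Cyp26a1, -4.58 for Fgfr2 and -3.74 for Irs4. Genes that rose more in mESC also had negative values. These were -4.70 for Igf2, -2.98 for Hand1, -3.23 for Rhox6, -2.42 for Krt8, -2.16 for Sox17, -2.93 for Col4a2, -3.00 for Plac1, -2.67 for Krt14, -1.87 for Acta2 and -1.06 for Hprt. The difference was positive for genes that rose more in AntNPC. It was 3.21 for Cdkn2a, 2.37 for Cldn6, 0.88 for Hoxa7, 1.54 for Hoxb8, 1.00 for Vax1, 2.36 for Zic1, 1.22 for Foxc1, 1.62 for Tfap2a, 2.04 for Dlx5 and 1.11 for Tgfb1. It was 2.64 for Esrrb, 1.48 for Tbx3, 3.75 for Utf1, 3.78 for Epcam and 3.90 for Gpx2, and 2.75 for Ephx2, 2.30 for Dhx16 and 3.27 for Dpys, which fell in mESC.

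Genes of chromosomes 3, 6 and 8 of mean FPKM above 5 lay higher as a group than other autosomal genes in the libraries labelled EED-/- of both cell types. Bias by GC content and transcript length is argued against by a smallest shift of 0.45 after regression on both, and the release of genes silent in WT cells by 0.46 among genes of at least 20 FPKM in both WT groups. Extra copies of these chromosomes in the line may be the source, but the smallest shift over the chromosomes, cell types and 6 libraries, 0.38, restates the pattern and decides nothing. Whole copies alone, at 0.58 for 3 over 2, do not give the medians within chromosome 6, which were 1.38 in both cell types for 38 genes at 60 to 80 Mb and -0.19 in AntNPC for 24 genes in the first 20 Mb, where mESC medians over 5 Mb of 4 to 7 genes went from -0.34 to 0.65. DNA was not analysed here, and with 1 line per genotype a trait of the line cannot be told apart from the loss of EED.

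Eed had more FPKM and a lower mean read count in AntNPC labelled EED-/-. Exchanged genotype labels are argued against by the Hox genes, known PRC2 targets, of which 27 of 27 were higher in AntNPC labelled EED-/-. Reads confined to a short part of Eed, as from a disrupted allele, may raise FPKM if the length used was short: reads per FPKM were 0.201 of those in WT, as low in only 2 of 11090 genes, for an implied length of 0.332 kb against 1.51 kb in WT. The rule written for this explanation asked for a length not below the shortest annotated Eed transcript. That transcript has 0.454 kb, so by the rule the value of 0.332 kb counts against the explanation. The range from the 10th to the 90th percentile of 595 single-transcript genes, 0.303 to 0.744 kb, includes 0.454 kb, but it was added after the value was seen. No reads along the gene were analysed here, so the explanation cannot be told apart from others.

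In mESC, WT replicate 2 and EED-/- replicate 1 resembled each other (r = 0.941 across genes) more than either resembled its own group (0.89 and 0.916). An exchange of their labels is argued against by a score of the genes changed at least 2-fold in AntNPC, on which the lower EED-/- mESC library stood 0.77 above the higher WT one. A preparation batch shared by the genotypes, with the numbers crossed in mESC, may be the source and stays open: the correlation of 0.5 between the deviations of EED-/- mESC replicate 2 and EED-/- AntNPC replicate 1 only mirrors, in a group of 2, the -0.5 of replicate 1 that prompted it. With the numbers crossed in the block 2441 genes rose and 344 fell in mESC. The mESC titles part the libraries only by number, as in AntNPC, and name no batch. The crossed batch was not tested further, and no biological explanation was tested.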

How the results depend on the processing

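The crossed block, the tests without chromosomes 3, 6 and 8, with zeros replaced, of the second deposition, of AntNPC alone with the block, and without mESC libraries of highest or lowest total were chosen after the results were seen.

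No named gene past the threshold reversed under the alternatives run. List medians that changed sign under quantile normalization were as follows. In AntNPC those of PRC1 (-0.04) and postmitotic neuron genes (-0.11) turned negative, and that of WNT targets went from 0 to -0.30. In the interaction those of PRC1 (0.05), postmitotic neuron (0.13), posterior neural (0.01) and sex chromosome line marker genes (0.41) turned positive, as did that of PRC2 subunits in EED-/- differentiation (0.02). In mESC medians turned negative for pan-neural (-0.24, with 1 rising and 4 falling in place of 4 and 0), study target (-0.01, 0 and 1 in place of 1 and 0), postmitotic neuron (-0.20) and cell cycle inhibitor genes (-0.15). After median-ratio scaling medians turned in mESC for proliferation (-0.06) and cell cycle inhibitor genes (-0.05), in WT differentiation for proliferation (-0.07), and in the interaction for posterior neural (0.06), postmitotic neuron (0.11) and sex chromosome line marker genes (0.23). In AntNPC 40 of 43 named genes kept their side of the threshold in every setting, in the interaction 19 of 19, in WT differentiation 23 of 24, in EED-/- differentiation 16 of 19 and in mESC 0 of 25. All 25 were lost when only the 4 mESC libraries were used, a fit with few residual degrees of freedom. The interaction compares all 4 groups, so the setting of the compared groups alone was not run for it. It rests on the same mESC groups of 2, and its 19 of 19 cannot be set against the 0 of 25. Sox1 in AntNPC passed in the second deposition alone (-0.34, adjusted p = 0.00238) and with AntNPC alone and the block (-0.28, 0.0241), and Six3 passed in the second deposition (1.24, 1.35e-06).

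With the replicate block 697 genes fell in AntNPC, 1735 rose and 190 fell in mESC, 938 rose and 1383 fell in EED-/- differentiation, and 275 and 776 differed in the interaction. The overlap of WT-induced genes with genes lower in AntNPC was 568, and that of genes higher in both cell types 820. The block assumes that numbers pair libraries, while the mESC deviations of equal number correlated at -0.67. Among list calls the block added BMP and TGF-beta in mESC (0.0474) and Hox and trophoblast in WT differentiation (0.549, 0.602 and 0.48 with an estimated correlation), took away pan-neural in the interaction, and changed no other. Beyond the fewer degrees of freedom, the cause was not tested.

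With the libraries of the compared groups alone 4323 rose and 2800 fell in AntNPC, and 0 and 0 in mESC (limma, 1703 at an unadjusted p under the threshold). AntNPC alone with the block gave 4549 and 3051, and the second deposition alone 5511 and 4125. The spread then comes from AntNPC libraries alone, which correlated more closely within groups than mESC libraries did. Without the 2 mESC libraries of highest total, 4537 rose and 1588 fell in mESC, and 1998 and 3718 differed in the interaction. Without those of lowest total the counts were 4109 and 789 in mESC, 3916 falling in WT differentiation, 4629 and 4412 in EED-/- differentiation, and 1001 and 2938 in the interaction. In both settings each mESC group has a lone library, which is assumed to vary like the other groups.

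Quantile normalization, which forces equal distributions, gave 1945 falling genes in AntNPC, 1216 rising and 1113 falling in mESC, and 841 downward differences. Median-ratio scaling gave 750 falling in mESC. Without the genes of chromosomes 3, 6 and 8, fewer genes being tested, 1657 rose in AntNPC, 740 were higher in both cell types, and 5 lists differed in the interaction in place of 8. A fold of at least 2, a stricter rule, left 1252 rising and 410 falling in AntNPC, 1726 and 194 in mESC, 2675 and 1607 in WT and 1024 and 1406 in EED-/- differentiation. It left overlaps of 337 and 544.

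Camera called 13 lists in AntNPC, 7 in mESC, 6 in WT and 9 in EED-/- differentiation and 8 in the interaction. With an estimated correlation 7, 2, 0, 0 and 0 held: anterior neural, Hox, mesoderm, endoderm, trophoblast, neural crest and stress in AntNPC, and endoderm and trophoblast in mESC. Calls also weakened where the estimate was below the preset 0.01. For stress genes in AntNPC it was 0.001, and the unadjusted camera p went from 0.00308 to 0.0138. The losses in this setting therefore cannot be put down to correlation between genes alone. Fry, which does not compare a list with other genes, called 22, 18, 15, 13 and 11.

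Leaving out 1 library at a time, 2048 to 3272 genes rose and 768 to 1669 fell in AntNPC, and 2323 to 3904 rose and 282 to 1366 fell in mESC. In WT differentiation 3580 to 5316 rose and 2121 to 3201 fell, and in EED-/- differentiation 941 to 3119 and 1537 to 3343. In the interaction 376 to 1558 differed upward and 1114 to 2733 downward. The counts moved by over 1.5 times only without a mESC library. A lone mESC library left by this is assumed to vary like the other groups, and the cause was not tested. The depth in reads per library is unknown, so no limit from depth can be given.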

Other observations

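The test of p53 target genes was chosen after the result was seen.

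Trp53, Cdkn1a and Ccng1 fell in AntNPC labelled EED-/-, and Eda2r, Ephx2 and Ccng1, further p53 targets, in mESC. A candidate explanation is lower expression of p53 targets in general. It was tested on 28 other targets. In AntNPC 12 of them fell and 2 rose, with a median log2 change of -0.66 (camera p = 1.39e-05; 0.139 with an estimated correlation). In mESC 8 fell and 1 rose, with a median of -0.86 (6.34e-11; 0.0385 with an estimated correlation). Among those that fell in both were the apoptosis genes Bbc3 and Aen and the stress gene Sesn2, while Pmaip1, another apoptosis gene, rose by 2.69 in AntNPC. The test leaves the explanation open, since in AntNPC it holds only with the preset correlation and some targets went the other way. A difference between the parental lines would give the same values and was not tested.

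Hprt was low in both WT groups, 0.513 ± 0.0614 FPKM (SD, n = 2) and 0.844 ± 0.29 FPKM (SD, n = 4), and high in both groups labelled EED-/-, 79.6 ± 4.48 and 46.4 ± 9.98 FPKM. Mid1 showed the opposite order, 328 ± 32.5 and 371 ± 69.2 FPKM in WT against 1.96 ± 0.936 and 4.93 ± 0.552 FPKM. E14 sublines in wide use lack a working Hprt gene. If the WT line is one of them, the Hprt RNA of every library labelled EED-/-, 37.9 to 82.8 FPKM, argues against descent of that line from it. Changes between the genotypes could then be differences between lines. The parental line of the EED-/- cells is not given in the sources used here, and DNA was not analysed.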
